A study of Mus musculus with 12 samples.

How the data were processed

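RNA from mouse ankle tissue was measured on 12 Affymetrix arrays, 1 for each of 3 strains at 0, 1, 2 and 4 weeks of infection with Borrelia burgdorferi, the bacterium of Lyme disease. The strains were C3H, C57BL/6 and C57BL/6 IL10KO, by its label a C57BL/6 strain whose Il10 gene is altered. Per the labels, total RNA was labelled with biotin by the standard Affymetrix procedure. The labels do not say how many animals went into an array, which allele the IL10KO mice carried, or when each array was run.

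The deposited values are probe set signals on a linear intensity scale, made by the authors with MAS5, whose version is not stated. The mean signal of each array, without the lowest and highest 2% of probe sets, lay close to 500.0, so the authors had scaled each array to a common level. The values come in 2 tables. The first holds 45101 probe sets on the 8 C57BL/6 and IL10KO arrays, and the second holds 22690 probe sets on the 4 C3H arrays, all of which are also in the first. Strain C3H and array type therefore cannot be told apart, so C3H signals are given and drawn beside the others only as values, and strains were compared by changes within a table. Detection calls were not used.

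Signals below a floor were raised to it before taking log2. The floor was the 40th percentile, over a table's arrays, of the probe sets that both tables hold: 210.0 in the 8-array table and 129.8 in the C3H table. Probe sets were named from the array annotation of 2016. Of the 45101 probe sets, 34958 had 1 symbol, 932 had several and 9211 were not listed, and 34754 of those with 1 symbol matched a gene record by gene ID. Probe sets with several symbols or none were left out. Each gene was read from the probe set with the highest mean log2 signal among those in both tables, or among all of its probe sets where both tables held none. This gave 18194 genes, 12394 of them also in the C3H table. A gene counted as measured when its signal was above the floor on at least 2 arrays of a table, which held for 11086 genes in the 8-array table, 8932 in the C3H table and 8027 in both.

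With 1 array per strain and week there is no replicate, so a comparison of 2 arrays has no test and no error. A gene was called higher or lower when the ratio of floored signals was 2 or more. Where the weaker signal lay under the floor, the ratio is a lower bound and is written as at least. For genes with other probe sets above the floor, these were checked for the same direction. The 28 gene lists, with 545 genes of which 506 matched a gene on the arrays by current or older symbol, covered interferon responses, immune cell types, skin, muscle, cartilage, bone, other tissues and metabolism. They were written from general knowledge before the data were examined, as were the comparisons, the tests, the floor and the rule for naming genes. That a current symbol is never read as an older name of another gene was set after the data were seen, and took 1 gene out of the glycolysis list. A list is described by the number of its measured genes that were higher or lower, by its median log2 fold change, and by the percentile of that median among 10000 random lists of the same size, matched on mean signal in 20 bins. The percentile is a description, since genes of a list are not independent.

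Genes named in a comparison were taken from the 10 highest and 10 lowest fold changes and from up to 4 members of each list. For changes shared by strains the 15 with the largest smallest change were eligible, for differences in response the 10 largest each way, and in fitted models the 10 largest past the threshold. Il10 is always named. Genes outside these rules are named only where the text says that they were chosen after their values were seen.

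Replication was available only across weeks and genotypes. A linear model with genotype and week as factors was fitted to the 8 C57BL/6 and IL10KO arrays with limma, with 3 residual degrees of freedom, eBayes with a trend, and Benjamini-Hochberg adjustment at 0.05 over 11086 genes. Its residual holds array noise and any difference between genotypes in the course of infection. Lists were tested in this model with camera at a preset correlation of 0.01 and again with an estimated correlation. The estimated form also tests on the residual degrees of freedom of the fit, so few lists can pass in it whatever their correlation. For each list, genes past 0.05 when adjusted over that list alone were also counted. This count was not among the planned tests. It is a description, since it is not adjusted over lists and contrasts and genes of a list are not independent. The model was tested on simulated data in which 200 genes were shifted: at a log2 shift of 1 it recovered 91% of them for genotype, 43% for week 1, 49% for week 2 and 52% for week 4, and at a log2 shift of 2 it recovered 100.0%, 94%, 96% and 98%. It also called 10, 2, 16 and 13 genes that had not been shifted. The simulated noise was independent between genes and arrays, with the moderated standard deviations of the fit. It held no difference between genotypes in the course of infection, so these shares do not give the power on the real arrays.

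Poly-A control RNAs, which are added to samples before labelling, split the 8 arrays into 5 with them and 3 without, described with the results. This split is called the labelling batch. Arrays on the same side of the split were not shown to have been labelled together. The arrays without the controls are the infected IL10KO arrays, so a block for it also takes up any response to infection particular to IL10KO. It was found in the values, and everything that uses it was chosen after the data were seen: a fit with the batch as a block (2 residual degrees of freedom), and comparisons with week 1 as the control. Alternatives planned beforehand were quantile normalization, scaling each table's arrays to a common median, floors at the 20th and 60th percentiles, no floor with 1 added before log2, the mean over all probe sets of a gene, eBayes without the trend, genotype without week, all infected against both uninfected arrays, leaving out each week, and camera with an estimated correlation. Leaving out single arrays in the week contrasts was added later. A model that let genotypes differ in late infection was also tried after the data were seen, gave unstable counts across settings and is not reported. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Gene order along chromosomes was taken from the GRCm38.p6 annotation and used only to find which genes neighbour Il10.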

Results

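The data describe ankle tissue from C3H, C57BL/6 and IL10KO mice before infection with Borrelia burgdorferi and 1, 2 and 4 weeks after it, with 1 array per strain and week. C3H mice are known to develop severe Lyme arthritis and C57BL/6 mice mild arthritis, and Il10 encodes a cytokine that restrains inflammation. The series title states an interest in pathways that go with arthritis of differing severity. Of the probe sets that both tables hold, between 59.5% and 60.6% lay above the floor on the C57BL/6 and IL10KO arrays and between 58.2% and 61.8% on the C3H arrays, shares that the definition of the floor largely fixes. The number of arrays, 1 per group, limits the precision of each pairwise value. Xist, transcribed from the inactive X chromosome, had a signal of 1556 or more on all 12 arrays, while the Y-linked gene Eif2s3y stayed under the floor on all 12 and peaked at 31.2.

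The arrays differed in a technical respect that partly follows the groups. Poly-A control RNAs had a geometric mean signal of 1848 to 2109 on the 4 C57BL/6 arrays and 2362 on the uninfected IL10KO array, but 16.6, 10.5 and 14.7 on the IL10KO arrays of weeks 1, 2 and 4. The 4 C3H arrays read between 12.9 and 22.3. Changes within C57BL/6, changes within C3H, the uninfected IL10KO and C57BL/6 pair, and changes among the infected IL10KO arrays thus stay inside 1 labelling batch, whereas IL10KO week 1, 2 or 4 against any other 8-array sample crosses it. The ratio of 3' to 5' signal for Gapdh, which rises as RNA degrades, was 1.18, 1.93, 2.81 and 1.28 on the C3H arrays of weeks 0, 1, 2 and 4, and 0.822 to 0.916 on the others.

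**Figure D1:**
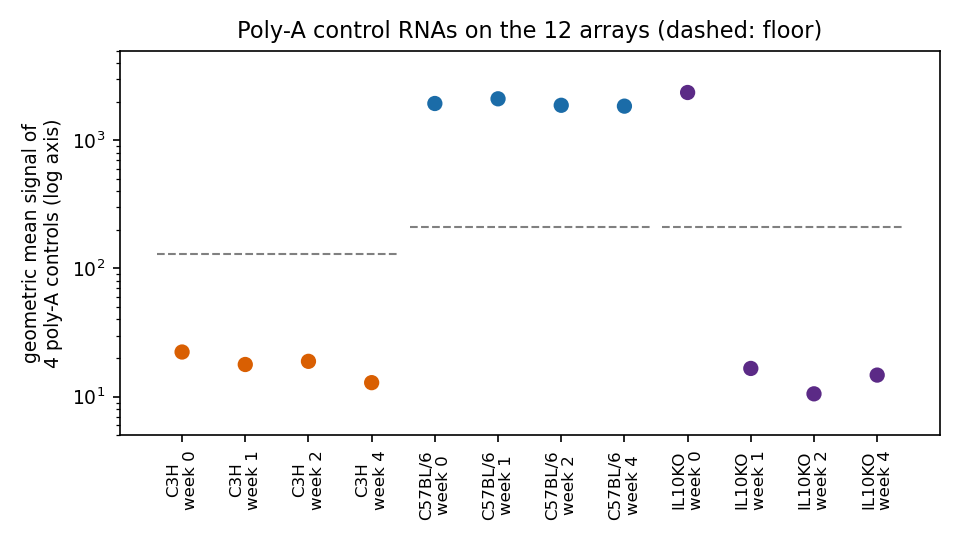
Geometric mean signal (MAS5 units, log axis) of 4 poly-A control RNAs on each of the 12 arrays, with points coloured by strain and dashed lines at each table's floor (129.8 for C3H, 210.0 for the others). The 4 C57BL/6 arrays and the uninfected IL10KO array lie at 1848 or above, and the other 7 arrays at 22.3 or below.

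Il10 itself was not lower on the arrays labelled IL10KO. Its signal on the C57BL/6 arrays was 63.0, 36.7, 206.5 and 83.6 at weeks 0, 1, 2 and 4, all under the floor, while the arrays labelled IL10KO read 309.6, 331.2, 1246 and 1186. The C3H values were 46.6, 118.0, 43.9 and 80.9, under the floor as well. The Il10 signal was thus higher in the arrays labelled IL10KO than in C57BL/6 at all 4 weeks. The labels do not give the allele, so whether the probe set lies outside the altered part of the gene is not known, and IL10KO below means the arrays labelled so.

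Which genes differ early in infection in C3H ankles was read from week 1 against uninfected C3H. The largest increases were in interferon-inducible GTPases, which act against intracellular microbes: Irgm2 read 7708 against 131 (59.0-fold higher), Iigp1 13709 against 298 (46.0-fold), Igtp 21992 against 537 (41.0-fold) and Gbp6 5517 against 229 (24-fold). Of 21 measured interferon-gamma-inducible genes, 15 were higher and 0 lower, and the list median of 2.22 (log2) lay above all 10000 random lists. Of 21 type I interferon-inducible genes 13 were higher, with a median of 1.09 and with Parp14 5.25-fold and Rtp4 4.38-fold higher. Cd274, the immune checkpoint ligand PD-L1, was at least 13.7-fold higher. Epidermal differentiation genes were lower for 17 of 24, with a median of -2.50: the keratins Krt10 and Krt1 were 47.8-fold and 30.2-fold lower, and Krt2 at least 44.5-fold lower. Extracellular matrix genes were lower for 9 of 22 (median -0.92), with the collagens Col1a1 3.91-fold and Col1a2 2.93-fold lower. Mast cell markers were lower for 4 of 6 (median -1.06), among them Cpa3 at 2.84-fold. Skeletal muscle genes leaned the other way, with 4 of 29 higher, a median of 0.60, and Ryr1 3.13-fold and Myh4 2.84-fold higher. Monocyte and macrophage markers had a median of -0.16, with 1 of 18 higher. In total 306 genes were higher and 515 lower, and scaling to a common median moved the share that was higher from 37.3% to 47.7%. The Gapdh 3' to 5' ratio was 1.93 on this array against 1.18 at week 0, which goes with each of these groups. Other probe sets bore out the direction at 1.5-fold for 20 of 85 higher and 61 of 151 lower genes that had one.

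By week 2 macrophage, interferon, osteoclast, matrix and cell division genes were higher in the C3H ankle than in the uninfected one, and epidermal and muscle genes lower. Of 18 monocyte and macrophage markers 15 were higher, with a median of 2.09: Aif1 was 18.4-fold, Ms4a7 9.19-fold and the lysozyme gene Lyz2 7.50-fold higher, and Clec4d at least 10.6-fold. Slc13a3, a dicarboxylate transporter, was at least 57.9-fold higher, the acute phase gene Saa3 19.7-fold, and Cxcl13, a chemokine that attracts B cells, 19.4-fold. Matrix and wound repair genes were higher for 12 of 22 (median 1.25), including the matrix metalloproteinases Mmp3 (14.5-fold) and Mmp13 (10.3-fold), the protease inhibitor Timp1 (6.82-fold) and Postn (5.42-fold). Of 7 osteoclast genes 4 were higher (median 1.32), with the bone-resorbing enzyme Acp5 at 3.30-fold. Cell cycle genes were higher for 9 of 16 (median 1.10), with Mki67, a marker of dividing cells, at 3.91-fold. Interferon-gamma-inducible genes were higher for 13 of 21, with a median of 1.48 and with Irgm2 at 7.13-fold. Lower were 16 of 24 epidermal genes (median -1.18), 15 of 29 skeletal muscle genes (median -1.01; Ckmt2 4.94-fold and Tnnc1 4.52-fold lower) and 3 of 6 erythroid genes (median -1.15). In all, 640 genes were higher and 631 lower. The Gapdh 3' to 5' ratio of 2.81 on this array, the highest of the 12, goes with each of these groups. Against week 1 instead of week 0 the macrophage and matrix medians were 2.02 and 2.14, that of the interferon-gamma list was -0.71, and that of the epidermal list was 0.88, with 12 of 24 genes higher and 0 lower.

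At week 4 the matrix and chemokine differences in C3H were still present while the interferon genes were closer to their uninfected level than before. Matrix and wound repair genes were higher for 15 of 22 (median 1.31), with Mmp13 12.1-fold, Mmp3 11.1-fold and Postn 4.96-fold higher. Tendon genes were higher for 3 of 6 (median 0.94), with Tnmd, encoding tenomodulin, at 3.24-fold. Chemokines and cytokines were higher for 8 of 20 (median 0.71, against 1.05 at week 2), with Cxcl13 21.0-fold higher and Cxcl10 at a log2 fold change of 0.00, and macrophage markers were higher for 11 of 18 (median 1.32), with Aif1 at 6.72-fold. Of 12 B and plasma cell genes 3 were higher (median 0.17), among them Jchain, which joins IgM and IgA subunits, at 10.8-fold and Ighm, the IgM heavy chain, at 2.67-fold. The interferon-gamma list had 6 of 21 higher and a median of 0.47. Epidermal genes were again lower, 19 of 24 with a median of -2.35, with Krt1 49.5-fold and Krt14 at least 25.8-fold lower. The totals were 369 higher and 408 lower.

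C57BL/6 ankles answer the same question in a strain with mild arthritis, and all 4 arrays share 1 labelling batch. At week 1 the largest differences were in skin genes: 23 of 31 epidermal genes were higher (median 1.77, above all random lists), with Krt1 at 6190 against 309, Krt2 14.4-fold and Krt10 13.5-fold higher, and filaggrin (Flg) at least 18.8-fold and Lce1c, a gene of the cornified envelope, at least 22.0-fold higher. None of 22 interferon-gamma-inducible, 26 type I interferon-inducible or 19 macrophage genes passed 2-fold, and each of these lists had a median of 0.00. Genes under the floor on both arrays give 0.00, so these medians do not show an absence of change. Saa3 was at least 2.34-fold higher. The matrix list was shifted to -0.24 with 0 of 22 genes past 2-fold, and 2 of 13 cartilage genes were lower, the growth-plate collagen Col10a1 by 2.83-fold and Col11a2 by 2.42-fold. In all 86 genes were higher and 31 lower, a split that depends on the floor (351 higher and 432 lower with the floor at the 20th percentile), and other probe sets bore out 10 of 23 and 1 of 12.

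At week 2 the C57BL/6 ankle showed macrophage, interferon and antigen presentation genes together. Slc13a3 was at least 48.6-fold higher, Cxcl13 at least 39.2-fold (8222 against 103) and Slamf9, a receptor of myeloid cells, 14.2-fold. Macrophage markers were higher for 16 of 19 (median 1.71), with Fcgr1 7.75-fold, Adgre1 6.48-fold and Ms4a7 5.75-fold higher. Interferon-gamma-inducible genes were higher for 16 of 22 (median 1.63), with Gbp2 8.34-fold, Iigp1 5.76-fold and the peptide transporter Tap1 5.20-fold higher and the chemokine Cxcl9 at least 7.24-fold. MHC class II genes were higher for 6 of 8 (median 1.59), with H2-Eb1 at 3.86-fold and Cd74 at 3.46-fold. Nfkbiz, a regulator of NF-kappaB, was 10.6-fold and Tlr2, the receptor for bacterial lipoproteins, 4.67-fold higher. Cell cycle genes were higher for 6 of 18 (median 0.81), with Birc5 at 2.70-fold. Epidermal genes were higher than at week 0 for 19 of 31 (median 1.28), but against week 1 their median was -0.47, with 0 higher and 3 lower. Neutrophil markers had a median of -0.20, with 2 of 17 higher. The lowest genes included Actc1 (4.33-fold lower) and Pdk4 (3.06-fold), and the totals were 378 higher and 38 lower, with other probe sets bearing out 95 of 132 higher genes. The share that was higher, 90.9%, was 60.7% with the floor at the 20th percentile and 51.9% with no floor.

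At week 4 in C57BL/6 the skin genes were at their highest, and the antibody genes Ighm and Jchain were higher. Epidermal genes were higher for 26 of 31 (median 2.37), with Krt1 at 35.6-fold (11010 against 309), Krt10 at 23.5-fold and Krt2 at 21.5-fold. Of 3 measured hair follicle genes 1 was higher (median 0.19), the keratin gene Krt25 by at least 6.31-fold. Ighm was 11.4-fold and Jchain at least 8.38-fold higher, in a B and plasma cell list with 3 of 9 genes higher and a median of 0.00. Macrophage markers were higher for 11 of 19 (median 1.14), with Lyz2 at 3.57-fold, and Cxcl13 was at least 11.9-fold higher. The interferon-gamma list had 2 of 22 higher and a median of 0.55. Col10a1 was at least 3.99-fold and Actc1, cardiac actin, 3.63-fold lower. In all 204 genes were higher and 32 lower, and the share that was higher, 86.4%, was 54.9% with the floor at the 20th percentile and 46.4% with no floor.

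**Figure D2:**
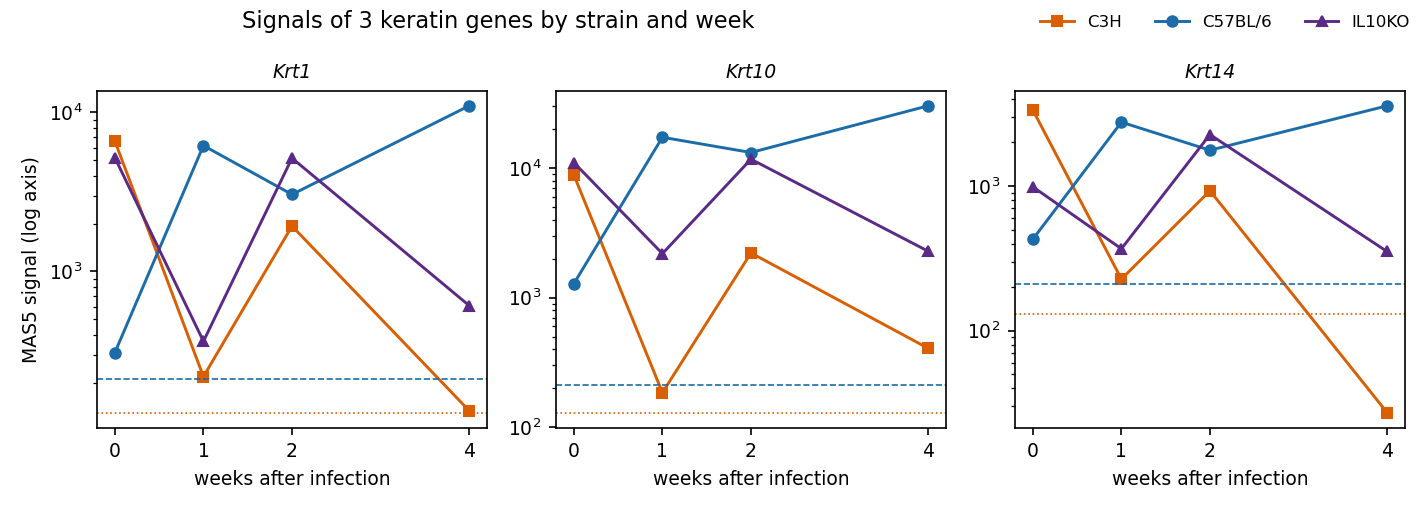
Signals (MAS5 units, log axis) of the keratin genes Krt1, Krt10 and Krt14 against weeks after infection, 1 array per point, with lines joining the arrays of C3H (squares), C57BL/6 (circles) and IL10KO (triangles); the dashed line is the floor of the 8-array table and the dotted line that of C3H. Krt1 goes from 309 to 11010 between weeks 0 and 4 in C57BL/6, from 6601 to 133 in C3H and from 5194 to 611 in IL10KO.

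In the arrays labelled IL10KO, week 1 against week 0 crosses the labelling batch. Genes of neutrophil granules were higher: Prtn3 3.75-fold, Ctsg 3.58-fold, Mpo 3.48-fold and Lcn2 2.66-fold, with 5 of 17 neutrophil markers higher and a median of 0.53. Saa3 was at least 3.87-fold higher. The interferon-gamma list had a median of 0.46 with 2 of 22 genes higher, Gbp3 at 2.53-fold and Gbp2 at 2.25-fold. Pdk4, which limits glucose oxidation, was 4.40-fold higher. Epidermal genes were lower for 14 of 31 (median -0.92), with Krt1 14.3-fold and Flg 10.1-fold lower, and cartilage genes were lower for 3 of 13 (median -0.37), among them Col11a1 at 3.55-fold and Chad at 2.34-fold. The totals were 74 higher and 118 lower, and common median scaling moved the share that was higher from 38.5% to 28.2%.

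At week 2 the IL10KO ankle showed a larger interferon response by list median than any C3H or C57BL/6 sample, though Iigp1 was higher by more in C3H at week 1. Of 22 interferon-gamma-inducible genes 21 were higher, with a median of 4.03 against week 0 and 3.50 against week 1 inside the labelling batch. Cxcl9 was at least 98.9-fold higher (20769 against 88.3) and Cxcl10 at least 42.7-fold, both chemokines that attract T cells, and Gbp2 was 33.7-fold and Iigp1 27.3-fold higher. Type I interferon-inducible genes were higher for 24 of 26 (median 2.12, and 1.86 against week 1), with Oasl2 at 12.4-fold. Saa3 was at least 70.2-fold higher and the complement gene Cfb 13.2-fold. MHC class II genes had a median of 2.27 (1.99 against week 1), with H2-DMa 13.0-fold and H2-Ab1 10.7-fold higher. Macrophage markers were higher for 16 of 19 (median 2.05, and 1.95 against week 1), with Aif1 at 22.9-fold and Marco, a scavenger receptor, at least 15.8-fold. T and NK cell markers were higher for 7 of 15 (median 0.88 against either week), with Ccl5 at least 43.6-fold and the cytotoxic granule genes Gzmb at least 5.15-fold and Nkg7 at least 4.18-fold. Neutrophil markers were higher for 13 of 17 (median 1.37, and 0.64 against week 1), with Chil3 at 8.02-fold. Cell cycle genes were higher for 13 of 18 (median 1.43, and 1.18 against week 1), with Top2a at 4.59-fold.

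Skeletal tissue genes were lower in the same IL10KO week 2 array. Cartilage genes were lower for 8 of 13, with a median of -1.62 against week 0 and -0.96 against week 1 of the same batch: Chad, encoding the cartilage protein chondroadherin, was 13.3-fold, Col9a1 4.17-fold and Col11a1 3.70-fold lower. The Wnt inhibitor Wif1 was 13.7-fold lower. Bone matrix genes were lower for 4 of 9 (median -0.89, and -0.40 against week 1), with Omd 4.46-fold and Ibsp 4.08-fold lower, and Fmod of tendon was 3.53-fold lower. Adipocyte genes were lower for 5 of 15 (median -0.77, and -0.89 against week 1), with Scd1 at 3.20-fold. Epidermal genes had a median of 0.00 against week 0 and 0.58 against week 1. In all 836 genes were higher and 556 lower against week 0, and 918 and 660 against week 1, with other probe sets bearing out 256 of 325 higher genes.

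At week 4 the interferon genes of IL10KO were as high as at week 2, and the antibody genes Ighm and Jchain and muscle genes differed as well. The interferon-gamma list had 21 of 22 genes higher and a median of 4.06 (3.53 against week 1), with Cxcl9 at least 109.8-fold, Cxcl10 at least 57.5-fold and Gbp2 31.4-fold higher. Chemokines and cytokines were higher for 16 of 22 (median 2.20 against either week), with the monocyte chemokines Ccl8 at 29.8-fold and Ccl2 at least 17.7-fold. Macrophage markers were higher for 16 of 19 (median 2.12, and 2.54 against week 1). Igkv8-30, an antibody light chain segment, was 27.0-fold, Jchain 10.8-fold and Ighm 5.65-fold higher, while the B and plasma cell list had 3 of 9 genes higher, 1 lower and a median of 0.65. Matrix and wound repair genes were higher for 5 of 22, Mmp3 by 19.6-fold, Timp1 by 4.15-fold and Mmp13 by 2.97-fold, but the list median was 0.02 (0.52 against week 1). Skeletal muscle genes were lower for 12 of 31 (median -0.95, and -0.76 against week 1), with the slow troponin Tnnt1 3.52-fold and Actn2 3.21-fold lower, and oxidative phosphorylation genes for 5 of 22 (median -0.72, and -0.69 against week 1). Cartilage genes were lower for 7 of 13 (median -1.09), but the median against week 1 was -0.31. Epidermal genes were lower for 16 of 31 (median -1.35), and their median against week 1 was 0.00. The totals were 858 higher and 707 lower against week 0, and 921 and 726 against week 1.

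**Figure D3:**
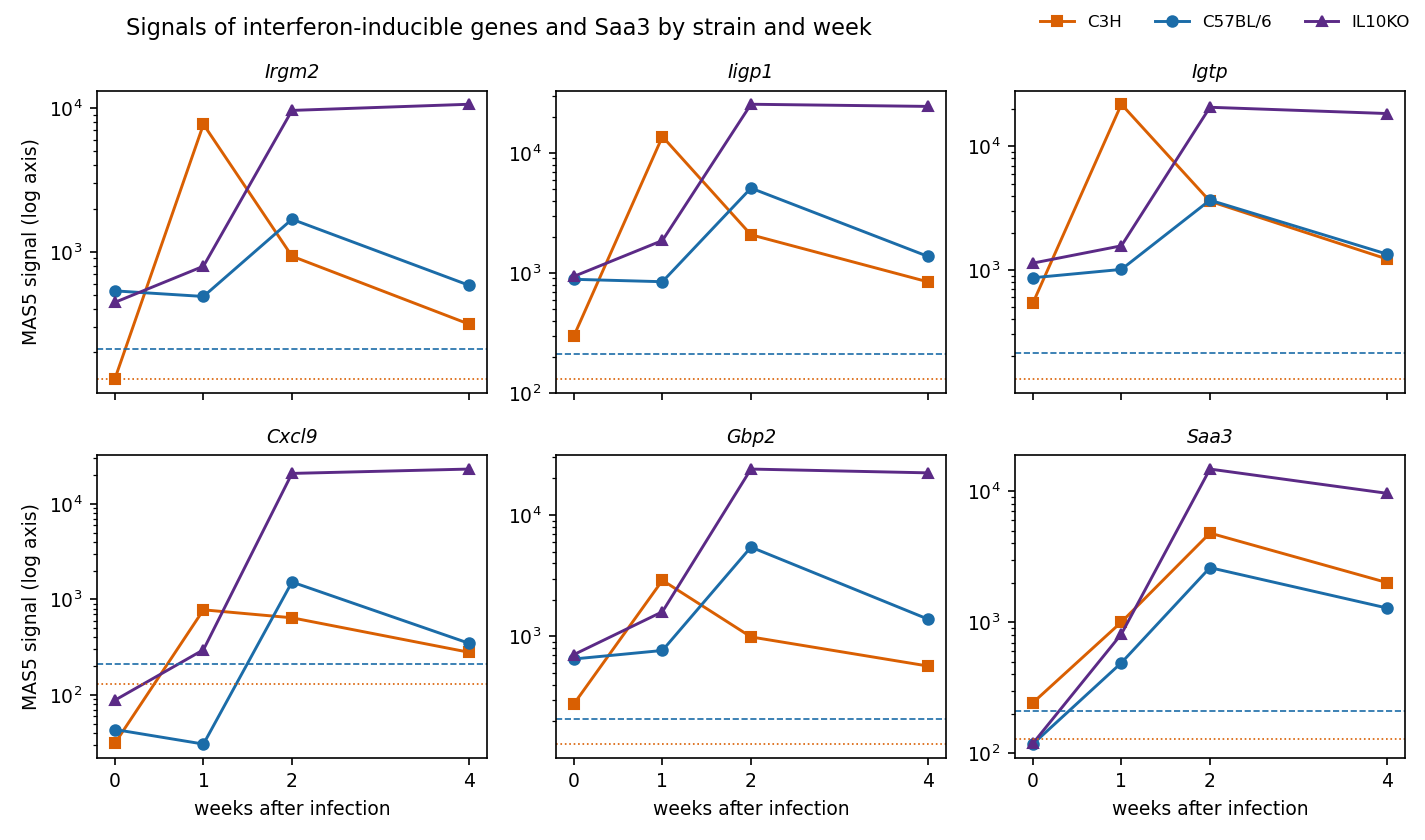
Signals (MAS5 units, log axis) of the interferon-inducible genes Irgm2, Iigp1, Igtp, Cxcl9 and Gbp2 and of Saa3 against weeks after infection, 1 array per point, with lines joining the arrays of a strain; the dashed line is the floor of the 8-array table and the dotted line that of C3H. Irgm2 peaks at week 1 in C3H (7708), at week 2 in C57BL/6 (1684) and stays high at weeks 2 and 4 in IL10KO (9632 and 10631).

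How the arrays labelled IL10KO differ from C57BL/6 was read week by week. Before infection, with both arrays in 1 labelling batch, Pam, which encodes an enzyme that amidates peptides, was 10.8-fold higher in IL10KO (5743 against 530.3). Skin genes were higher too, 16 of 31 with a median of 1.16, with Krt1 at 16.8-fold and Krt10 at 8.59-fold. Neutrophil markers were higher for 4 of 17 (median 0.41), with the antimicrobial peptide gene Camp at 3.22-fold and S100a9 at 2.56-fold. Of the adipocyte genes, Thrsp was 2.47-fold and Fasn 2.33-fold higher (2 of 15, median 0.52). None of 22 interferon-gamma-inducible genes passed 2-fold and their median was 0.00, which does not show an absence of difference where both signals lie under the floor. Mcm6, a helicase subunit for DNA replication, was 2.95-fold lower. In all 112 genes were higher and 44 lower. Il10 read 309.6 against 63.0, higher on the array labelled IL10KO.

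From week 1 on, the 2 strains lie in different labelling batches, so strain and batch cannot be told apart in these pairs. At week 1 Pam was 9.07-fold higher in IL10KO, and neutrophil markers were higher for 11 of 17 (median 1.38), with the granule enzymes Prtn3 5.37-fold and Mpo 5.24-fold higher. Cd1d1, which presents lipids to NKT cells, was 4.84-fold higher. Interferon-gamma-inducible genes were higher for 6 of 22 (median 0.51), with Gbp3 at 3.16-fold. Erythroid genes had a median of 0.64, above all random lists, with 0 of 9 past 2-fold. Epidermal genes were lower for 23 of 31 (median -1.74), with Krt1 17.0-fold and Flg 15.2-fold lower. The totals were 72 higher and 138 lower, and Il10 read 331.2 against 36.7.

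At week 2 the interferon-gamma list was higher in IL10KO for 21 of 22 genes, with a median of 2.41: Cxcl9 was 13.7-fold, Cxcl10 9.95-fold and Cd274 8.27-fold higher, and Gbp2b at least 19.7-fold. Within batches the change from week 1 to week 2 had a list median of 3.50 in IL10KO and 1.76 in C57BL/6. Neutrophil markers were higher for 14 of 17 (median 2.27), with S100a9 12.3-fold, Chil3 10.6-fold and Mpo 8.73-fold higher. Type I interferon-inducible genes were higher for 20 of 26 (median 1.39). Macrophage markers differed less, with 5 of 19 higher and a median of 0.47. Cxcl13 was 17.6-fold lower in IL10KO (468 against 8222), the largest decrease. Cartilage genes were lower for 9 of 13 (median -1.09), with Chad at 8.93-fold. Malat1, a nuclear RNA, was 5.42-fold lower, and its signal followed the batch, at 9676 to 16451 on the 5 arrays with poly-A controls and 2629 to 3104 on the 3 without. In all 417 genes were higher and 323 lower, and Il10 read 1246 against 206.5.

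At week 4 the separation was widest. The interferon-gamma list was higher in IL10KO for 21 of 22 genes (median 3.70), with Cxcl9 at 66.4-fold, Cxcl10 at 38.0-fold, Cd274 at 22.1-fold and Gbp6 at 20.3-fold. From week 1 to week 4 within batches the list median was 3.53 in IL10KO and 0.55 in C57BL/6. Macrophage markers were higher for 11 of 19 (median 1.28; Aif1 8.77-fold), chemokines for 15 of 22 (median 1.85; Ccl8 13.0-fold) and pattern recognition genes for 11 of 18 (median 1.12; Clec7a, the beta-glucan receptor, 5.78-fold). T and NK cell markers were higher for 7 of 15 (median 0.83), with Gzmb at least 7.55-fold. Mmp13 was 6.02-fold and Mmp3 5.84-fold higher. Epidermal genes were lower for 26 of 31 (median -2.85), with Flg 21.9-fold and Krt2 16.2-fold lower, and all 3 measured hair follicle genes were lower (median -2.03). Skeletal muscle genes were lower for 11 of 31 (median -0.83), with Tnni1 at 3.44-fold. In all 759 genes were higher and 652 lower, and Il10 read 1186 against 83.6.

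**Figure D4:**
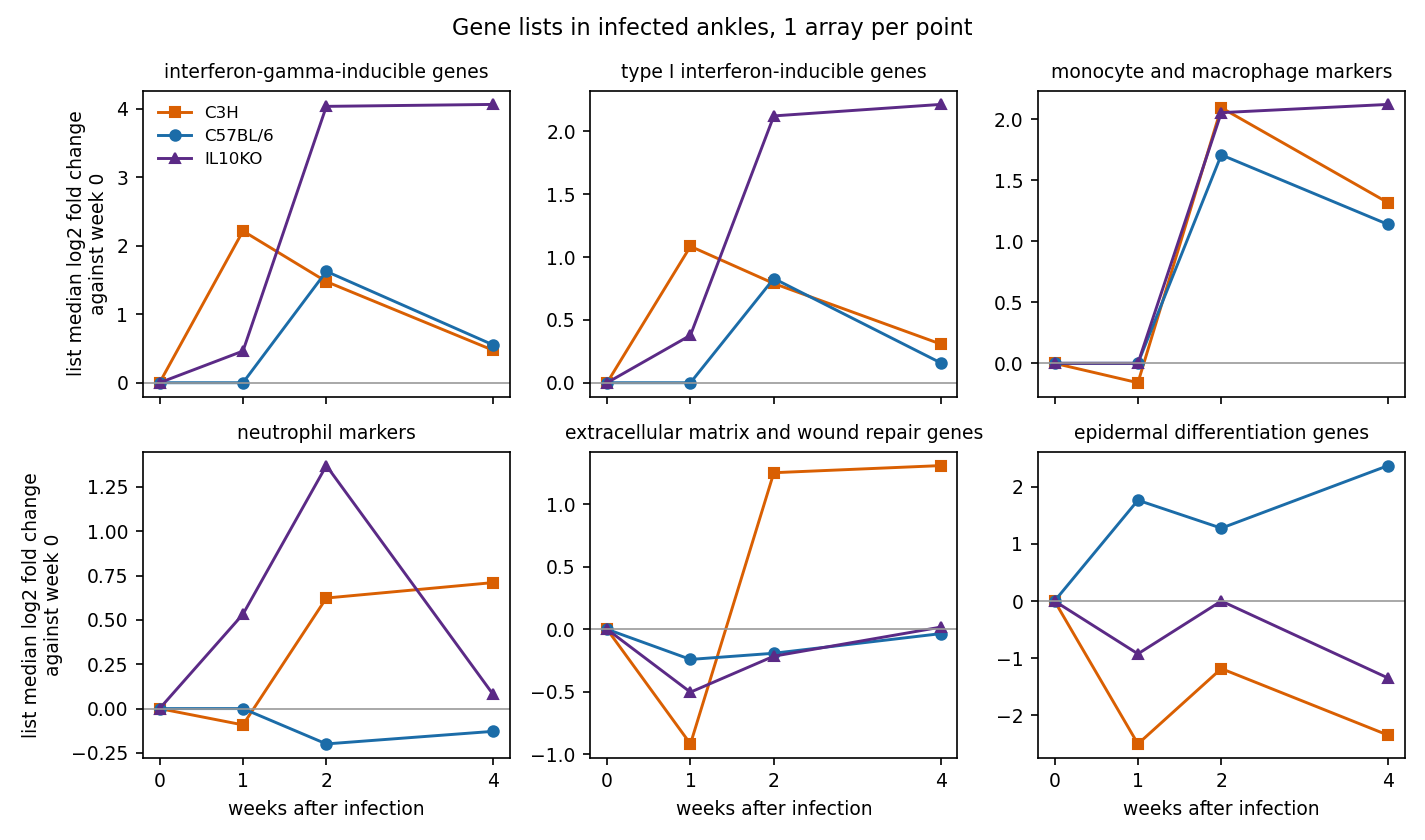
List median log2 fold change against week 0 (vertical axis) by weeks after infection (horizontal axis) for 6 gene lists, 1 array per point, with lines joining the arrays of C3H (squares), C57BL/6 (circles) and IL10KO (triangles) and a grey line at 0. The interferon-gamma list is at 2.22 in C3H at week 1 and at 4.06 in IL10KO at week 4, and the epidermal list is at 2.37 in C57BL/6 and -2.35 in C3H at week 4.

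The responses of the 3 strains were set side by side over the 8027 genes measured in both tables. Log2 fold changes here and in the next paragraph are of floored signals. Where the weaker signal lay under the floor, they are lower bounds in size. At week 2, 178 genes were higher in all 3 strains, where 1.92 would be shared by independent lists of the same sizes. Those with the largest smallest change were Slc13a3, Saa3 (log2 fold changes of 4.30 in C3H, at least 3.64 in C57BL/6 and at least 6.13 in IL10KO) and Aif1, followed by genes of myeloid or B cells: Clec4a2 (3.12, 3.23 and 2.76), Slamf9 (3.19, 3.83 and 2.75), Cd72 and Mpeg1. Frzb, a Wnt antagonist of cartilage, was the 1 gene lower in all 3 (0.086 by independence). At week 4, 51 genes were higher in all 3 strains against 0.539 by independence, among them Slc13a3, Saa3, Jchain (3.44, at least 3.07 and 3.43) and Igkv8-30 (2.28, 3.91 and 4.75). At week 1 only Saa3 and Mt2, a metallothionein gene, were higher in all 3 (0.012 by independence).

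Responses that parted the strains included interferon-inducible, matrix and skin genes. The largest differences between C3H and C57BL/6 were in skin genes, such as Krt10 (-5.58 against 3.75 at week 1) and Krt1 (-5.63 against 5.15 at week 4). At week 1 interferon-inducible genes led the excess of C3H over C57BL/6, such as Irgm2 (5.88 against -0.13) and Iigp1 (5.52 against -0.07), and Irgm2, Igtp and Iigp1 also led the excess of C3H over IL10KO (0.83, 0.47 and 0.99 in the latter). By weeks 2 and 4 the order had turned between C3H and IL10KO: Cxcl10 was at 0.99 and 0.00 in C3H and at least 5.42 and 5.85 in IL10KO, and Cxcl9 at 2.31 and 1.11 against at least 6.63 and 6.78. Matrix and wound repair genes had list medians of 1.25 and 1.31 at weeks 2 and 4 in C3H, -0.19 and -0.035 in C57BL/6 and -0.21 and 0.02 in IL10KO: Mmp13 was at 3.36 at week 2 against 0.29 in C57BL/6, Lum at 2.73 at week 4 against -0.36, and Postn at 2.44 and 2.31 at weeks 2 and 4 against -0.38 and -0.27, while Mmp3 at week 4 was at 3.48 in C3H and 4.29 in IL10KO. Counted over all 8027 genes, 41 were higher in C57BL/6 and lower in C3H at week 1 (3.24 by independence), 27 at week 2 (21.5) and 51 at week 4 (5.88), skin genes among them, such as Krt1 (4.32 against -4.92 at week 1). At week 1, 47 genes were lower in both C3H and IL10KO (4.75 by independence). None of these differences in response was tested, since each rests on single arrays.

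Across weeks, the limma fit compared IL10KO with C57BL/6 using week as a factor. Pam was higher in IL10KO by 3.24 (log2, SE 0.170, adjusted p = 0.00424), and at 4 of 4 weeks, with a signal of 3613 or more against 556 or less. It was the 1 gene of 11086 past the threshold, and 2157 had an unadjusted p under 0.05. No gene passed with the labelling batch as a block (limma, 523 unadjusted), where Pam was at 3.44 with an adjusted p of 0.980, nor without week 0 (2248 unadjusted) or without week 1 (2159). Of 22 interferon-gamma-inducible genes 18 were higher in IL10KO when adjusted over the list alone and 0 over all genes, with a list median of 1.80. Camera gave an adjusted p of 1.05e-10 with the preset correlation and an adjusted p of 0.614 with an estimated correlation. Of 17 neutrophil markers 13 were higher in IL10KO over the list alone (adjusted p = 3.15e-11, and adjusted p = 0.614 with an estimated correlation), as were 12 of 14 acute phase and antimicrobial genes (median 1.26, adjusted p = 1.78e-09, and 0.614 as the adjusted p with an estimated correlation) and 8 of 9 erythroid genes (median 0.61, adjusted p = 2.55e-05, and 0.614 as the adjusted p with an estimated correlation). In all 15 lists passed camera with the preset correlation and 0 with an estimated one, and with the batch as a block 5 passed. In the block fit, which draws the genotype difference from week 0 alone, 0 genes of these 4 lists were higher over the list alone: the interferon-gamma median was 0.00 (adjusted p = 0.937), the neutrophil median 0.41 (adjusted p = 0.00689), the acute phase median 0.33 (adjusted p = 0.0136) and the erythroid median 0.093 (adjusted p = 0.0979), each with an adjusted p of 0.994 with an estimated correlation. Il10 read higher on the arrays labelled IL10KO at all 4 weeks and the allele is not known, so the direction is that of arrays labelled IL10KO.

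The same limma fit gave the changes that both genotypes shared, with 2 arrays per week. By week 4, 4 antibody genes rose, each higher on both week 4 arrays: Igkv8-30 by 4.33 (SE 0.276, adjusted p = 0.0153), Jchain by 3.25 (SE 0.250), Ighm by 3.01 (SE 0.254) and Ighg3 by 2.41 (SE 0.198), the last 3 with an adjusted p of 0.0244. With the labelling batch as a block 0 genes passed (627 unadjusted), with these genes at 4.17, 3.07, 3.35 and 2.40 and an adjusted p of 0.759. Of the 9 B and plasma cell genes 2 passed at week 4, with a median of 0.54 (camera adjusted p = 0.00276, and adjusted p = 0.507 with an estimated correlation) and of 0.35 with the block. Their signals in C3H, which was not in the fit, were also higher at week 4 than at week 0: Igkv8-30 at 3082 against 635 and Ighm at 6906 against 2591. No gene passed at week 1 (367 unadjusted) or week 2 (1823 unadjusted), nor in all infected against both uninfected arrays (619 unadjusted). The week 4 count was 175 (154 higher, 21 lower) without C57BL/6 week 4 and 0 without any 1 of C57BL/6 week 0, IL10KO week 0 or IL10KO week 4.

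Among lists in the week contrasts of the fit without the block, macrophage markers had the largest share of genes that rose over the list alone at weeks 2 and 4. At week 2, 17 of 19 rose when adjusted over the list alone and 0 over all genes, with a median of 1.88 (adjusted p = 2.42e-18 with the preset correlation, and adjusted p = 0.509 with an estimated correlation), and at week 4 16 of 19 with a median of 1.64 (adjusted p = 9.01e-18, and adjusted p = 0.507 with an estimated correlation). Interferon-gamma-inducible genes rose for 17 of 22 over the list alone at week 2 (median 2.90, adjusted p = 3.56e-13, and adjusted p = 0.509 with an estimated correlation) and for 13 of 22 at week 4 (median 2.34, adjusted p = 2.48e-12, and adjusted p = 0.507 with an estimated correlation). Cell cycle genes rose for 14 of 18 over the list alone at week 2 (median 1.23, adjusted p = 7.41e-12, and adjusted p = 0.509 with an estimated correlation). With the batch as a block the macrophage medians were 1.92 and 1.53 and the interferon-gamma medians 1.72 and 1.24 at weeks 2 and 4, but fewer genes rose over the list alone: 13 and 7 of 19 macrophage markers and 0 and 0 of 22 interferon-gamma-inducible genes at weeks 2 and 4, and 2 of 18 cell cycle genes at week 2, whose median was 0.77 (adjusted p = 1.35e-09, and adjusted p = 0.561 with an estimated correlation). Of 27 lists, 8, 18 and 17 passed camera at weeks 1, 2 and 4 with the preset correlation, and 0 at each week with an estimated one. At week 1 the matrix list had a median of -0.37 with 0 of 22 genes past the threshold over the list alone (adjusted p = 7.67e-07, and adjusted p = 0.648 with an estimated correlation).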

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

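All tests of explanations in this part were chosen after the results were seen.

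Epidermal differentiation genes moved one way on every infected C57BL/6 array and the other way on every infected C3H array. Their list medians against uninfected were 1.77, 1.28 and 2.37 (log2) at weeks 1, 2 and 4 in C57BL/6, and -2.50, -1.18 and -2.35 in C3H. In IL10KO, by its label a C57BL/6 strain, they were -0.92, 0.00 and -1.35, in comparisons that cross the labelling batch. The C57BL/6 direction was thus not seen in IL10KO. None of these differences was tested, since each median rests on 2 arrays.

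For these epidermal genes, labelling batch, meaning only the split by poly-A controls, is argued against. C57BL/6 weeks 0 and 4 both have the controls and the median between them was 2.37. Other labelling differences among arrays with the controls stay open, since the labels do not say when each array was run. RNA quality of the C3H arrays is argued against only as the whole cause: the array with the highest Gapdh 3' to 5' ratio, week 2, had the smallest decrease, and the median at week 4 lay at -1.16 relative to week 2. A part in the decrease stays open. Week 1, with the next highest ratio (1.93), had the largest decrease, and every infected C3H array had a ratio above that of week 0 (1.18). A different share of skin in the dissected ankle could raise or lower all skin genes together, and it cannot be told apart from a response of the epidermis: from week 0 to week 4 in C57BL/6 the median was 3.37 over 25 suprabasal genes but 0.57 over 9 basal layer genes, among which Krt14 (3.06) and Krt5 (2.70) moved with the suprabasal genes while Itgb4 (-0.68), Itga3 (-0.20) and Dst (-0.05), which other tissues express as well, did not. A further set of 20 skin genes, assembled after the values were seen and overlapping the suprabasal kind, had the list's sign in 10 of 10 comparisons, which leaves both open. A biological difference between strains in the skin over the joint stays untested, and the uninfected C57BL/6 array, low in Krt1 at 309 against 5194 in uninfected IL10KO, enters all 3 C57BL/6 medians.

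Interferon-gamma-inducible genes were higher in IL10KO at weeks 2 and 4 than in uninfected IL10KO and than in C57BL/6. Labelling batch, meaning only the split by poly-A controls, is argued against as the cause of the rise within IL10KO. Weeks 1 and 2 both lack the controls and the median between them was 3.50. Other labelling differences among the arrays without the controls stay open. More macrophages are argued against only as the whole cause of the difference from C57BL/6: macrophage markers had a median of 0.47 between IL10KO and C57BL/6 at week 2, where the interferon-gamma list had 2.41. This pair crosses the labelling batch, and the 2 lists need not scale alike with the share of macrophages. Macrophage markers were also higher within IL10KO at weeks 2 and 4, so a part in the rise there stays open. Ifng itself, named after its values were seen, read 472 and 708 on the IL10KO arrays of weeks 2 and 4 and stayed under the floor on the other 10. A hypothesis that may account for both is a stronger interferon-gamma response in IL10KO. It was found on these single arrays and was not tested.

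Pam and other genes differed the same way between IL10KO and C57BL/6 at all 4 weeks: 8 genes were 2-fold higher, 1 was 2-fold lower, and 54 passed 1.5-fold. Labelling batch, meaning only the split by poly-A controls, is argued against for Pam. Pam was already at 3.44 in the uninfected pair, where both arrays have the controls. Another labelling difference between the arrays of that pair stays open. A candidate explanation is a chromosome segment around Il10 that came with the altered allele. Pam, which prompted it, was left out. Of the 99 other measured genes nearest Il10 in GRCm38.p6, 4 were among the rest of the 54 (Chil1, Ctse, Cxcr4 and Rab7b). Of 10968 others, 49 were. The odds ratio was 9.38 (Fisher's exact p = 0.00126, two-sided). That count was reached by 68 of 10867 windows of that size apart from the one around Il10 (0.626%). Among genes that passed 2-fold the odds ratio was 37.7, resting on Chil1 and Ctse alone, and 0.929% of windows reached that count. The nearest 25 genes on each side, without Pam among them, held 3 of the 54 (odds ratio 13.7). All of chromosome 1 held 12, Pam included (odds ratio 4.75). Of these, Aff3, Bmpr2, Phf3 and Ube2w lie beyond the nearest 100 on each side. A segment limited to the genes near Il10 would not account for them. Neighbouring genes are not independent, and the list of genes near Il10 fixed beforehand, with medians of 0.07, 0.00, -0.01 and 0.00 at the 4 weeks and a camera adjusted p of 0.840 (adjusted p of 0.886 with an estimated correlation), decides nothing, since a segment would raise some genes and lower others. Chil1 and Cxcr4 are also genes of immune cells, and a difference caused by Il10 itself stays open.

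For the 1 gene past the limma threshold between genotypes, the arrays are matched by week, and 8 splits exchange arrays within all 4 weeks, too few for a share under 0.05: the real split gave 1 gene and the highest other 0. Of all 32 splits that could be fitted, 2 more gave genes, 1580 each. These 2 are the same fit with the sign turned, since both keep weeks 0 and 1 whole and compare the strains at weeks 2 and 4. At those weeks strain and labelling batch cannot be told apart. This fit is thus a late strain contrast that crosses the batch, and not a split by chance. The blocked fit of genotype gave 0 genes.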

How the results depend on the processing

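Labelling batch as a block, week 1 as the control and leaving out single arrays were chosen after the data were seen; the other alternatives were planned. Under the scaling, floor and probe set alternatives, 39 of 2090 list medians moved by over 1.5 times and 0 reversed, and of 9018 fold changes of single genes 1296 moved and 2 reversed. For these medians and those against week 1, reversed means that a median of 2-fold or more as reported changed sign. Sign changes of smaller medians were not counted as reversed. List directions did depend on the control array and on the block. The block marks exactly the infected IL10KO arrays. Batch and a response to infection particular to IL10KO therefore cannot be told apart in it. Against week 1 instead of week 0, 24 of 162 list medians moved and 3 reversed: in C3H at week 2 the interferon-gamma list from 1.48 to -0.71 and the epidermal list from -1.18 to 0.88, and in C57BL/6 at week 2 the epidermal list from 1.28 to -0.47. With the batch as a block, 42 of 108 list results in limma passed camera at the preset correlation instead of 58: 28 no longer passed and 12 newly did. The median changed sign in 27, of which 15 passed camera in neither fit. The other 12, called reversed, were, for genotype, epidermal (-0.83 to 1.16), skeletal muscle (-0.28 to 0.0720), cell cycle (0.32 to -0.00791) and oxidative phosphorylation genes (-0.15 to 0.32), and for week 1 type I interferon (0.18 to -0.48), interferon-gamma (0.25 to -0.84), neutrophil (0.26 to -0.22), skeletal muscle (-0.10 to 0.17), adipocyte (-0.08 to 0.27), cartilage (-0.34 to 0.0733), cell cycle (0.05 to -0.19) and oxidative phosphorylation genes (-0.07 to 0.22). Since the block takes up what the infected IL10KO arrays share, these changes of sign do not show an effect of labelling. Counts depended on the floor, since it decides how many weak signals can reach 2-fold: 39 of 39 pairwise counts under the floor alternatives moved by over 1.5 times, and 1 of 45 under the others. Under both scaling alternatives all 13 pairwise counts stayed within 1.5 times.

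Pairwise counts follow in the order C3H weeks 1, 2 and 4, C57BL/6 weeks 1, 2 and 4, IL10KO weeks 1, 2 and 4, and IL10KO against C57BL/6 at weeks 0, 1, 2 and 4. Which side held more genes turned in 16 of 84 alternatives. In C57BL/6 the splits depend on the floor: 73.5%, 90.9% and 86.4% were higher as reported at weeks 1, 2 and 4, 44.8%, 60.7% and 54.9% with the floor at the 20th percentile, and 44.2%, 51.9% and 46.4% with no floor. C3H week 2, with 640 higher and 631 lower, turned to 1270 and 1313 with the floor at the 20th percentile, 1632 and 1725 with no floor, and 452 and 458 with the mean of all probe sets. C3H week 4, with 369 and 408, turned to 406 and 306 with quantile normalization, 398 and 335 with common median scaling, 240 and 164 with the floor at the 60th percentile, and 867 and 690 against week 1. At week 4 IL10KO, with 858 and 707, turned to 1148 and 1392 with the floor at the 20th percentile and 2024 and 2914 with no floor, and IL10KO against C57BL/6, with 759 and 652, to 1061 and 1224 and to 2044 and 2617. That pair also turned with no floor at week 0 (112 and 44 to 1471 and 1505) and week 2 (417 and 323 to 1810 and 1834). As reported the counts were 821, 1271, 777, 117, 416, 236, 192, 1392, 1565, 156, 210, 740 and 1411. With the floor at the 20th percentile they were 2169, 2583, 1963, 783, 1178, 953, 731, 2334, 2540, 824, 704, 1414 and 2285. With the floor at the 60th percentile they were 361, 764, 404, 44, 229, 112, 112, 861, 1018, 59, 103, 447 and 908. With no floor they were 2934, 3357, 2796, 2896, 3303, 3195, 2951, 4498, 4938, 2976, 2849, 3644 and 4661. Against week 1 instead of week 0 the C3H week 4 count was 1557, and the cause was not tested.

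Genes higher in all 3 strains were 2, 178 and 51 at weeks 1, 2 and 4, and genes lower in all 3 were 0, 1 and 0. With the floor at the 20th percentile the week 1 count of higher genes was 7 and the counts of lower genes were 4, 10 and 6. With the floor at the 60th percentile, 1 gene was higher at week 1, 33 at week 4 and 0 lower at week 2. With no floor 40, 279 and 107 were higher and 39, 53 and 79 lower. Quantile normalization gave 1 higher gene at week 1, and common median scaling 1 lower gene at week 4. Dhx58 in IL10KO against C57BL/6 at week 2 was at 1.65, and at -0.29 with the floor at the 20th percentile and with no floor, since its probe set was then another one.

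In limma, genotype gave 1 gene, weeks 1, 2 and 4 gave 0, 0 and 4. Genotype gave 2 genes with the floor at the 20th percentile and 2 with no floor, week 2 gave 42 with no floor, and week 4 gave 0 with the floor at the 60th percentile (7631 genes tested) and 0 with the mean of all probe sets. With the batch as a block genotype and week 4 gave 0 and 0, with fewer degrees of freedom. Leaving out 1 week at a time, genotype ranged from 0 (without week 0, and without week 1) to 1, and leaving out 1 array at a time week 4 ranged from 0 to 175, the latter without C57BL/6 week 4; the cause was not tested. A week left with 1 array was assumed to vary like the others. Lists past the camera threshold were 15, 8, 18 and 17 for genotype and weeks 1, 2 and 4, and 0, 0, 0 and 0 with an estimated correlation. Lists with a low estimated correlation no longer passed either, such as the matrix list at week 1 (correlation 0.0641, camera adjusted p from 7.67e-07 to 0.648). Other lists had high estimated correlations in the fit without the block. They were 0.972 for interferon-gamma-inducible, 0.895 for type I interferon-inducible and 0.541 for cell cycle genes, and 0.519 for neutrophil and 0.475 for macrophage markers. For these lists the p-values with the preset correlation do not allow for correlation that high. The counts of 0 can thus reflect both correlation between genes and the few residual degrees of freedom of that form, and the parts were not separated. With the batch as a block genotype gave 5.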

Other observations

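The genes and strain comparisons in this part were chosen after the values were seen, while its lists were planned.

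Against week 0 of the same strain, Cxcl13 was at log2 fold changes of 4.28 and 4.39 in C3H at weeks 2 and 4, at least 5.29 and 3.58 in C57BL/6, and at least 1.16 and 2.04 in IL10KO. Gzmb read 1081 and 1585 on the IL10KO arrays of these weeks and stayed under the floor on all C57BL/6 arrays. T and NK cell markers had medians of 0.00 in C57BL/6 at each infected week, and 0.00, 0.00 and -0.02 in C3H. Since genes under the floor on both arrays give 0.00, these medians do not show an absence of change.

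Endothelial markers had a median between -0.30 and 0.16 over the 13 planned comparisons of 2 arrays. Glycolysis genes had medians of -0.39 in C3H, 0.03 in C57BL/6 and -0.61 in IL10KO at week 4. Immediate early and heat shock genes had medians of 0.09, 0.27 and 0.53 at week 4, with Fos 2.09-fold higher in C3H and 4.37-fold in IL10KO. In limma that list had medians of 0.39 and 0.33 at weeks 2 and 4, with camera adjusted p of 0.00564 and 0.00525 (adjusted p of 0.509 and 0.507 with an estimated correlation).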
